A study of Mus musculus with 15 samples.

How the data were processed

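RNA was measured in bone marrow-derived macrophages, the phagocytes grown from C57BL/6 mouse marrow in medium with the growth factor M-CSF. The cells were unstimulated or had received 100 ng/ml lipid A, the part of bacterial lipopolysaccharide that activates Toll-like receptor 4, for 15, 30, 60 or 120 min. Each time point had 3 fractions (chromatin, nucleoplasmic and cytoplasmic), which gave 15 libraries, 1 per fraction and time. The labels do not say whether the 3 fractions of a time point came from the same plates, or whether time points were separate cultures. Tests that pair the fractions by time rest on the time label alone. Per the labels' protocols, cells were opened with a mild detergent, nuclei were spun through sucrose, and nuclei were then lysed with more detergent and urea into a soluble nucleoplasmic part and a chromatin pellet. Total RNA was depleted of ribosomal RNA and made into strand-specific libraries with dUTP, also per the labels' protocols. Reads were aligned with TopHat to the mm9 build, per the submitters' processing notes. The TopHat version, the counting tool, the annotation and the treatment of reads with several matches are not given in the sources used here.

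The authors deposited RPKM values (reads relative to the length counted and to the size of the library), per the file headers, in 2 tables used here. The first held 10020 transcripts with values relative to exon length, every one of them at 1.00 RPKM or more in at least 1 library. The second held 560 genes with classes A1 to F and a promoter type, and each had at least 1 chromatin value 5.01-fold or more above its 0 min value. Its values were read as relative to the whole gene, introns included, from the lengths that turned them into whole reads. Another 3 columns of per-sample values matched no sample described in the labels and were not used.

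Values were turned back into reads to learn their depth. For 100% of the genes of both tables, 1 length per gene made all 15 values whole reads. The tolerance was 0.02 reads, and wider in proportion for values of many reads. The exon lengths found this way lay within 5% of a reference transcript for 67.8% of the 9850 genes with a reference length. The libraries then held 38.8 to 52.3 M reads for chromatin, 24.5 to 31.4 M for nucleoplasmic and 15.6 to 19.9 M for cytoplasmic RNA. At that depth 1 read in a gene of 1 kb was worth 0.0191 to 0.0642 RPKM. A value without reads had been replaced in the deposited table by the worth of 0.0191 RPM (the read count relative to the library), which was so for at least 318 values. In the chromatin library of 15 min that is also the worth of 1 read, so values without reads could not be told apart there. Intervals and floors (3 reads) cover counting error only, since PCR copies were not marked. Gene names and older names were matched through a RefSeq table of assembly GRCm38, and GENCODE transcripts gave transcript lengths and shared sequence. No coordinates were used because the builds differ.

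The change with lipid A was the log2 ratio of RPKM + 0.5 in a stimulated library to RPKM + 0.5 in the 0 min library of the same fraction, which understates the change of weakly expressed genes. Genes needed 1 RPKM in at least 1 library of the fraction. With 1 library per fraction and time there was no test, so a gene was called higher or lower at 4-fold or more at any of the 4 stimulated times. Redrawing the 0 min reads 100 times by counting alone gave 0 calls in every fraction. On simulated data, 6-fold changes were called for 92.0% of 50 genes in chromatin RNA (8881 genes), 88.0% in nucleoplasmic RNA (9317 genes) and 92.0% in cytoplasmic RNA (9239 genes). Simulated losses to 0.167 of the 0 min value were called for 28.0%, 68.0% and 46.0% of 50 genes in the same order, with 0 false calls. These simulations held counting error only, without shifts or other variation between libraries, so the 0 false calls cover counting error alone.

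Most genes shifted together within a fraction. The median ratio to the 0 min library, on the log2 scale, was -0.15, -0.34, -0.39 and -0.20 in chromatin RNA at 15, 30, 60 and 120 min. It was -0.07, -0.17, -0.15 and -0.42 in nucleoplasmic RNA and 0.01, 0.14, 0.47 and -0.48 in cytoplasmic RNA. Values rescaled by these shifts are called rescaled. They are given beside the counts over all genes and beside named genes that they bring under 4-fold, but only in part beside the counts and medians of lists and the times of highest values.

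Fractions were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with time point as a term, a trended prior, and Benjamini-Hochberg adjusted p under 0.05 together with a 2-fold difference. All 15 libraries entered, with the 9441 genes at 1 RPKM in at least 3 libraries. No library was replicated, so the 5 time points served as the values of a fraction. The p-values set a mean fraction difference against the variation between times left over in all 3 fractions together. That variation is between stimulation times, not between replicates. On data simulated for the cytoplasmic against chromatin comparison (9441 genes), shifts of 1, 1.5, 2 and 3 on the log2 scale were recovered for 50.0%, 94.0%, 100% and 100% of 50 genes each, with 1 false call.

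Intron to exon read density was computed for 477 genes found in both tables. Intron reads were those of the whole gene less those of the exons, and each was divided by its length. Genes needed 300 nt of introns, which 22 lacked, and 1 more had fewer reads over the whole gene than over its exons in some library, which left 454, and 20 exon reads in all 15 libraries, which left 305. This measure was chosen after the files had been seen. On simulated data for those 305 genes, densities of 0.5, 0.05 and 0.01 came back as 0.500, 0.0500 and 0.00983.

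The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, except where stated. The rule took, per fraction, the 10 highest and 10 lowest genes past 4-fold in the same direction at 2 or more times. Per fraction comparison it took the 10 highest and 10 lowest genes past the adjusted p with the same direction at all 5 times. It added up to 4 members of each list with the strongest values, and always Tnf, Fos, Egr1, Nfkbia, Il1b, Il6, Il12b, Cxcl1, Cxcl10, Ccl5, Ifnb1, Ifit1, Nos2, Actb, Gapdh and Malat1. Predicted genes, genes without a symbol and duplicated symbols were passed over. Where 5 or fewer members of a list passed, those outside the rule were in part named too, after their values had been seen. Results for some genes that this rule selected are not reported here; the counts and medians of the lists include them.

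The 27 gene lists were immediate early genes, chemokines, inflammatory cytokines, NF-kappaB feedback and targets, interferon-stimulated genes, the Toll-like receptor pathway, MAP kinase phosphatases and regulators, prostaglandin and nitric oxide synthesis, macrophage identity, chemotactic and surface receptors, glycolysis, cholesterol synthesis, cell cycle, cytoplasmic ribosomal proteins, oxidative phosphorylation, nuclear noncoding RNAs, snoRNA host genes, replication-dependent histones, splicing factors, signal recognition and secretory pathway, housekeeping reference genes, and markers of neutrophils, T cells, B cells, dendritic cells, erythroid cells and stromal cells. A list's median was placed among 10000 random lists of the same size matched on mean expression.

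The alternatives were other pseudocounts (0.1 and 1 RPKM), other minimum values, other fold sizes, rescaling, quantile normalization, a model without the time term, only the libraries of the fractions compared, the 15 min library as the baseline, and leaving out each time point. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.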

Results

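RNA of mouse bone marrow-derived macrophages was sequenced in 3 fractions at 5 times of lipid A stimulation (0, 15, 30, 60 and 120 min), which gave 15 libraries with 1 library per fraction and time. Chromatin RNA is the RNA of the chromatin pellet, nucleoplasmic RNA that of the soluble part of the nucleus preparation, and cytoplasmic RNA that outside it. The libraries held 46.0, 52.3, 42.2, 41.0 and 38.8 M reads in chromatin RNA from 0 to 120 min. The nucleoplasmic libraries held 25.5, 31.4, 24.8, 24.5 and 30.3 M reads and the cytoplasmic libraries 15.6, 16.8, 17.5, 18.2 and 19.9 M reads. Exons of the listed genes took 20.6% to 27.2% of chromatin reads, 54.5% to 60.8% of nucleoplasmic reads and 28.1% to 44.2% of cytoplasmic reads. Because no fraction and time was replicated, no difference between times has a replicate check, and the intervals given cover counting error only.

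The first comparison asked which transcripts differed in chromatin RNA after lipid A. Egr1, an immediate early transcription factor, stood at 1.14 RPKM at 0 min, 88.2 RPKM at 15 min and 0.386 RPKM at 120 min. Tnf, the inflammatory cytokine, went from 20.6 RPKM at 0 min to 414 at 15 min and 1158 at 30 min, 56.2-fold above its 0 min value (95% counting interval 53.4 to 59.2), and was at 552 RPKM at 120 min. Cxcl10, a chemokine that draws T cells, was highest at 120 min at 1281 RPKM against 4.11 RPKM, 311-fold higher (271 to 359). In all, 578 of 8881 genes were higher by 4-fold or more at some time and 347 were lower. Higher genes numbered 73, 191, 225 and 461 at 15, 30, 60 and 120 min, and lower genes 2, 30, 108 and 293. Without the 120 min library 285 were higher and 122 lower. The balance rests on the pseudocount: 0.1 RPKM gave 742 higher and 1028 lower, and 1 RPKM 468 and 159.

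The chromatin genes highest above 0 min included effectors of host defence, all at 120 min except Cxcl2, and Il12b at 60 min when rescaled. Their log2 ratios were 8.12 for Cxcl10, 8.10 for Irg1, the enzyme that makes itaconate, 7.65 for the chemokine Ccl5 and 7.51 for Gbp5, a guanylate-binding protein. Cd69, a lectin of activated leukocytes, had a log2 ratio of 7.28, Il12b, the shared subunit of interleukins 12 and 23, one of 7.23, and Nos2, the inducible nitric oxide synthase, one of 7.22. Rsad2, the antiviral enzyme viperin, had a log2 ratio of 7.18, the neutrophil chemokine Cxcl2 one of 7.09 at 30 min, and Il27 one of 7.01. Il12b rested on 9 reads at 0 min and Nos2 on 11, so the RPKM ratio of Il12b was 894 with a counting interval of 471 to 1956. Ifnb1, the interferon beta gene, had 1 read at 0 min and 22.1 RPKM at 60 min, a ratio of 781 with an interval of 140 to 30906.

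The genes lowest against 0 min in chromatin RNA were led by Cd300lb, an immunoglobulin-family receptor of myeloid cells, from 28.5 to 0.304 RPKM at 120 min (log2 ratio -5.17). Cxcr4, a chemokine receptor, had a log2 ratio of -4.82 and Zfp36l2, a protein that binds AU-rich mRNA, one of -4.31. The transcription repressor Bhlhe41 had a log2 ratio of -4.17, and Txnip, which binds thioredoxin, was lowest at 60 min at -4.12. Arhgap19, Lhfpl2, Lyl1, Rab3il1 and Gab3 followed with log2 ratios of -4.09, -4.08, -3.94, -3.89 and -3.87. All 10 stayed past 4-fold after rescaling, with the weakest at -3.66, while the number of lower genes was 220 rescaled and that of higher genes 687.

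**Figure D1:**
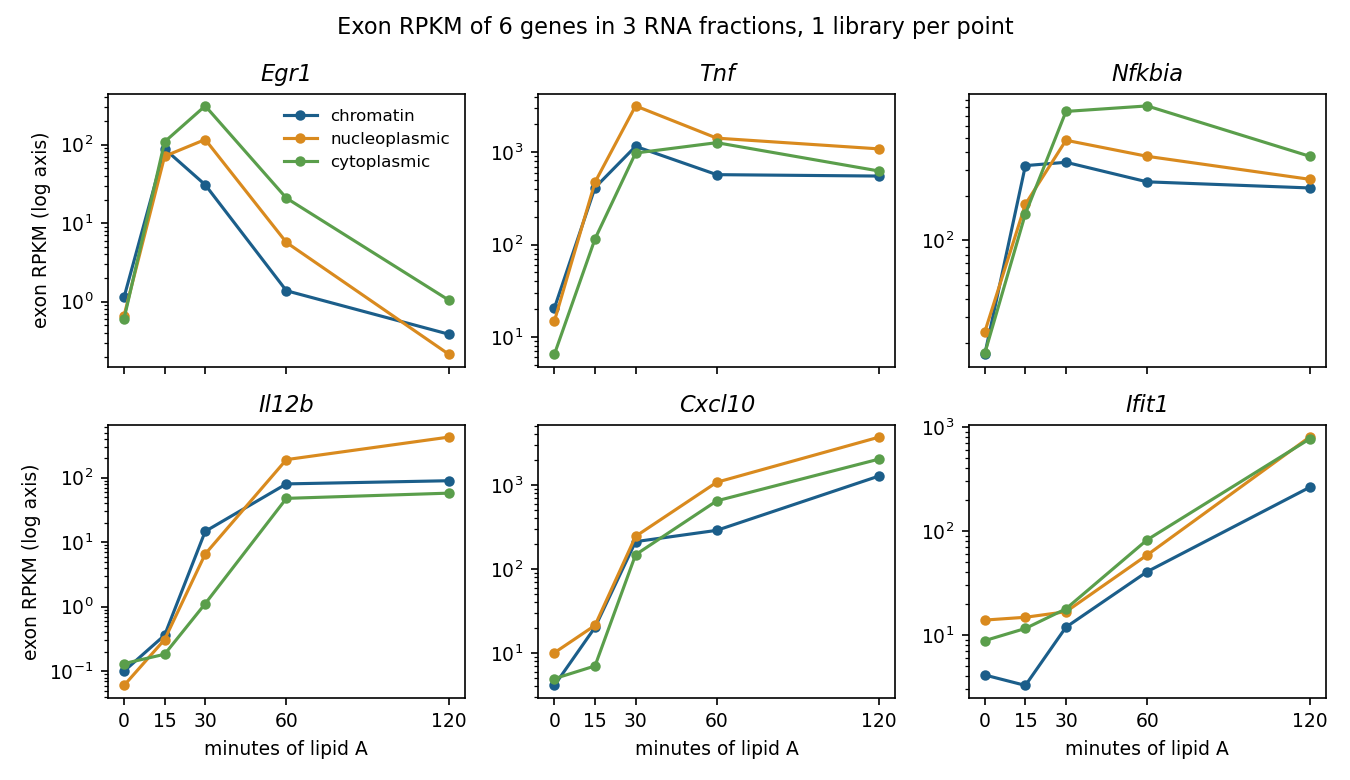
Exon RPKM (log axis) of 6 genes against minutes of lipid A in chromatin, nucleoplasmic and cytoplasmic RNA, with 1 library per point. Egr1 was highest at 15 min in chromatin RNA and at 30 min in the other fractions, while Cxcl10 and Ifit1 were highest at 120 min in all 3.

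Gene lists fixed in advance followed separate time courses in chromatin RNA. Of 21 measured immediate early genes, 16 were higher at some time and 0 lower, with a median log2 ratio of 2.97 at 15 min, 2.92 at 30 min and 0.13 at 120 min (3.07, 3.25 and 0.32 rescaled). Besides Egr1 they included Egr2, another factor of its family, at 4.74, the MAP kinase phosphatase Dusp1 at 4.51 and the transcription factor Junb at 4.40, all at 30 min. Fos, a part of the AP-1 transcription factor, was at 39.3 RPKM at 15 min against 4.57 RPKM. MAP kinase phosphatases and regulators had 8 higher and 1 lower of 10, with a median of 3.08 at 30 min and 0.29 at 120 min, and the lower gene was the ERK phosphatase Dusp6 at -3.62.

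NF-kappaB feedback and target genes stayed high from 30 min on. Higher values were found for 19 of 21, with medians of 1.60, 3.07, 3.05 and 3.27 at 15, 30, 60 and 120 min. Tnfaip3, a ubiquitin-editing inhibitor of NF-kappaB, had a log2 ratio of 6.25 at 30 min, the cytokine signalling inhibitor Socs3 one of 5.77 at 120 min, and Nfkbia, which encodes the inhibitor IkappaB alpha, one of 4.29 at 30 min. Chemokines had 16 higher of 17, with medians from 0.98 at 15 min to 3.99 at 120 min. Inflammatory cytokines had 19 higher of 19, with medians from 0.52 to 3.58 (4.71 with genes lacking 0 min reads at their bound), and Il6 stood at 82.1 RPKM at 120 min against 0.160 RPKM. Each of these medians lay at percentile 100 among 10000 matched random lists.

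Interferon-stimulated genes came last. Their median log2 ratio was 0.06 at 15 min, 0.09 at 30 min, 1.01 at 60 min and 4.11 at 120 min, and 25 of 30 were higher. Cmpk2, a nucleotide kinase next to viperin in the interferon response, had a log2 ratio of 6.60, the guanylate-binding protein Gbp2 one of 6.39, and Ifit1, which binds viral RNA, one of 5.84. In the prostaglandin and nitric oxide list, 5 of 13 were higher, namely Irg1, Nos2, Ptgs2, the inducible cyclooxygenase, at 6.83, Gch1 at 2.41 and the prostaglandin receptor Ptger4 at 2.13. Chemotactic and surface receptors had 9 higher and 2 lower of 20, with the costimulatory receptor Cd40 at 5.58 and the chemokine-binding receptor Ccrl2 at 5.34, while Cxcr4 was among the lower. Of the Toll-like receptor pathway, 3 of 25 were higher (Tlr2 at 3.38, Irak2 at 2.80 and Tlr3 at 2.54; 5 rescaled), and of macrophage identity genes 3 of 22 were higher (Cebpb at 2.97, Cd14 at 2.85 and Fcgr1 at 2.40) and 1 was lower.

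Metabolic and growth lists held few calls in chromatin RNA. Glycolysis had 3 higher of 17, the sugar transporter gene Slc2a6 at 4.03, Pfkfb3 at 2.89 and Hk2 at 2.08, and its median at 120 min was 0.72. Cholesterol synthesis had 0 calls among 17 (1 higher rescaled) with a median of -0.46 at 120 min, and oxidative phosphorylation 0 among 24 with a median of 0.43. Cell cycle genes also had 0 calls among 18 and a median of -0.95 at 120 min (-0.77 rescaled), with the mitotic kinase gene Bub1 at -1.99. Replication-dependent histones had 3 lower of 9 and a median of -1.20 at 120 min (-1.03 rescaled), namely Hist2h2be at -2.56, Hist1h1a at -2.13 and Hist1h1e at -2.04, of which only Hist2h2be stayed past 4-fold when rescaled, and these genes share sequence within their family. Among nuclear noncoding RNAs 2 of 6 were lower, the imprinted antisense RNAs Airn at -2.95 and Kcnq1ot1 at -2.20. Splicing factors had 1 higher of 26, Tra2a at 2.16, while snoRNA hosts had 0 calls among 7 (1 higher rescaled), the secretory pathway 0 among 18, housekeeping genes 0 among 16 and cytoplasmic ribosomal proteins 0 among 23.

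Most neutrophil markers were among the listed genes, while markers of the other cell types were few. Of the list markers, 8 of 13 for neutrophils, 3 of 12 for T cells, 2 of 10 for B cells, 1 of 10 for dendritic cells, 0 of 10 for erythroid cells and 1 of 12 for stromal cells were listed. In chromatin RNA none was higher, and Cd28, a costimulatory receptor of T cells, was lower, from 25.7 to 5.48 RPKM at 120 min, a log2 ratio of -2.13 (-1.93 rescaled, under 4-fold). Lck, a kinase of T cells, stood at 3.24 RPKM in cytoplasmic RNA at 120 min against 0.0910 RPKM, which was 3 reads (a ratio of 35.6 with a counting interval of 11.9 to 175), and the stromal marker Pdgfrb at 1.80 RPKM in nucleoplasmic RNA against 0.0435 RPKM (2.08). The neutrophil marker S100a9, an abundant calcium-binding protein that macrophages also make, was at 55.1 RPKM in cytoplasmic RNA at 60 min against 21.6 RPKM.

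The second comparison asked the same of nucleoplasmic RNA. Il12b had the highest log2 ratio, 9.57, from 3 reads at 0 min to 425 RPKM at 120 min, a ratio of 7053 with a counting interval of 2413 to 34202. The cytokine Il6 followed with a log2 ratio of 8.55 from 1 read at 0 min, a ratio of 5542 (994 to 218949). Tnf was at 3174 RPKM at 30 min, 213-fold above 0 min (197 to 231), and Cxcl10 at 3719 RPKM at 120 min. Of 9317 genes, 451 were higher and 262 lower, with 32, 94, 196 and 379 higher and 0, 2, 12 and 260 lower at 15, 30, 60 and 120 min. Rescaled counts were 579 higher and 148 lower, and without the 120 min library 202 were higher and 12 lower. A pseudocount of 0.1 RPKM gave 533 higher and 631 lower, and 1 RPKM 395 and 152.

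Further high genes in nucleoplasmic RNA were Cxcl2 with a log2 ratio of 8.51 at 30 min, Cd69 with 8.46, Cxcl10 with 8.46 and the acute-phase gene Saa3 with 8.21, the last from 4 reads. Ptgs2 had 8.07, the cytokine Il1b 8.07 at 60 min and Il27 8.03. The rule named 8 lower genes, with Cd300lb at -5.84, Lyl1 at -4.79, the cannabinoid receptor gene Cnr2 at -4.67 and Bhlhe41 at -4.36. Txnip was at -3.87, Dusp6 at -3.58, the arrestin-like gene Arrdc3 at -3.12 and Rgs2, a regulator of G protein signalling, at -2.18, and all but Txnip and Rgs2 were lowest at 120 min.

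In the nucleoplasmic lists, immediate early genes had 17 higher of 20 with a median of 3.66 at 30 min and 1 lower, the growth regulator Myc at -2.14 (-1.83 rescaled). MAP kinase phosphatases and regulators had 7 higher and 1 lower, Dusp6, of 10 with a median of 2.51 at 60 min, and NF-kappaB feedback and targets 18 of 21 with a median of 3.18 at 120 min. Chemokines had 15 higher of 17 with a median of 5.54 at 120 min (5.62 with genes lacking 0 min reads at their bound), and inflammatory cytokines 19 of 21 with medians of 4.01 at 60 min (4.58 at the bound) and 3.87 at 120 min, though the rescaled median was highest at 120 min at 4.25. Interferon-stimulated genes had 22 higher of 30, with medians of 0.32 at 60 min and 3.60 at 120 min. Surface receptors had 8 higher of 20 and 2 lower, among them Cxcr4 at -5.61. Prostaglandin and nitric oxide genes had 6 higher of 13, and the Toll-like receptor pathway 3 of 25, Tlr2 at 3.62, Irak2 at 2.48 and Tlr3 at 2.36 (6 rescaled). Of 23 macrophage identity genes Cd14 at 2.54 and Cebpb at 2.14 were higher, and Cebpa at -3.08, a transcription factor of the myeloid lineage, was among the lower. Glycolysis had 2 higher of 16, Slc2a6 at 2.87 and Pfkfb3 at 2.60, and splicing factors 1 of 24, Tra2a at 2.05. Among cell cycle genes Cdc20, an activator of mitotic exit, stood at -1.99. The lists of cholesterol synthesis, cell cycle, ribosomal proteins, oxidative phosphorylation, noncoding RNAs, snoRNA hosts, histones, the secretory pathway and housekeeping genes had 0 calls each.

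The third comparison followed cytoplasmic RNA. Il1b was highest above 0 min, from 0.339 RPKM (7 reads) to 463 RPKM at 60 min, a log2 ratio of 9.11. Irg1 reached 1125 RPKM at 120 min (log2 ratio 8.61), Cxcl10 2037 RPKM (8.55), and Egr1 311 RPKM at 30 min (8.14). Of 9239 genes, 414 were higher and 174 lower. At 15, 30, 60 and 120 min, 22, 90, 243 and 310 were higher and 0, 1, 2 and 174 lower, while rescaled counts were 510 higher and 97 lower in all. Without the 120 min library 249 were higher and 2 lower, and without both the 60 and 120 min libraries, left out after their common shift was seen, 90 and 1. A pseudocount of 0.1 RPKM gave 519 higher and 404 lower, and 1 RPKM 347 and 95.

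The other cytoplasmic genes named as highest were Cxcl2 with a log2 ratio of 8.38 and the chemokine Cxcl1 with 8.34, both at 60 min, and Ccl5 with 8.26 at 120 min. Nfkbiz, a nuclear regulator of NF-kappaB, had 7.80 at 60 min, Cd69 7.53 and Gbp5 7.52 at 120 min. Tnf was at 1270 RPKM at 60 min against 6.51 RPKM, and Nfkbia at 820 RPKM against 17.1 RPKM. Il1a, a cytokine related to Il1b, had 0 reads at 0 min and 72.6 RPKM at 60 min, at least 745-fold above the floor of 3 reads. The rule named 2 lower genes, Txnip at -3.65 and Arrdc3 at -2.85.

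In the cytoplasmic lists, immediate early genes had 18 higher of 22 with a median of 4.08 at 30 min, NF-kappaB feedback and targets 19 of 21 with 3.68 at 60 min and 3.33 at 120 min (3.22 and 3.81 rescaled), chemokines 16 of 17 with 5.05 at 120 min, inflammatory cytokines 16 of 20 with 3.30 at 120 min, and interferon-stimulated genes 21 of 30 with 3.48 at 120 min. With genes lacking 0 min reads at their bound, the chemokine median at 120 min was 5.37. MAP kinase phosphatases and regulators had 7 higher of 11 and 1 lower, Dusp6 at -3.11. Surface receptors had 7 higher of 19 and 2 lower, among them Cxcr4 at -3.74. Prostaglandin and nitric oxide genes had 4 higher of 12 (Irg1 at 8.61, Nos2 at 6.74, Ptgs2 at 5.44 and Ptger4 at 2.16, or 1.75 rescaled), and the Toll-like receptor pathway 3 of 25 (Tlr2 at 3.29, Irak2 at 2.44 and the kinase Map3k8 at 2.12; 7 rescaled). Of 22 macrophage identity genes Cd14 at 2.70 and Cebpb at 2.56 were higher, and Cebpa at -2.84 was among the lower. Splicing factors had 1 higher of 24, again Tra2a, at 2.29. Cell cycle genes had 0 calls among 18 with a median of 0.54 at 60 min and -0.91 at 120 min, which was 0.09 and -0.45 rescaled. Glycolysis, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, noncoding RNAs, snoRNA hosts, histones, the secretory pathway and housekeeping genes had 0 calls each, though rescaled 2 glycolysis genes were higher and 1 noncoding RNA lower. Actb, the beta-actin gene, was at 1137 RPKM at 0 min and 1577 RPKM at 120 min in cytoplasmic RNA, a log2 ratio of 0.47.

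**Figure D2:**
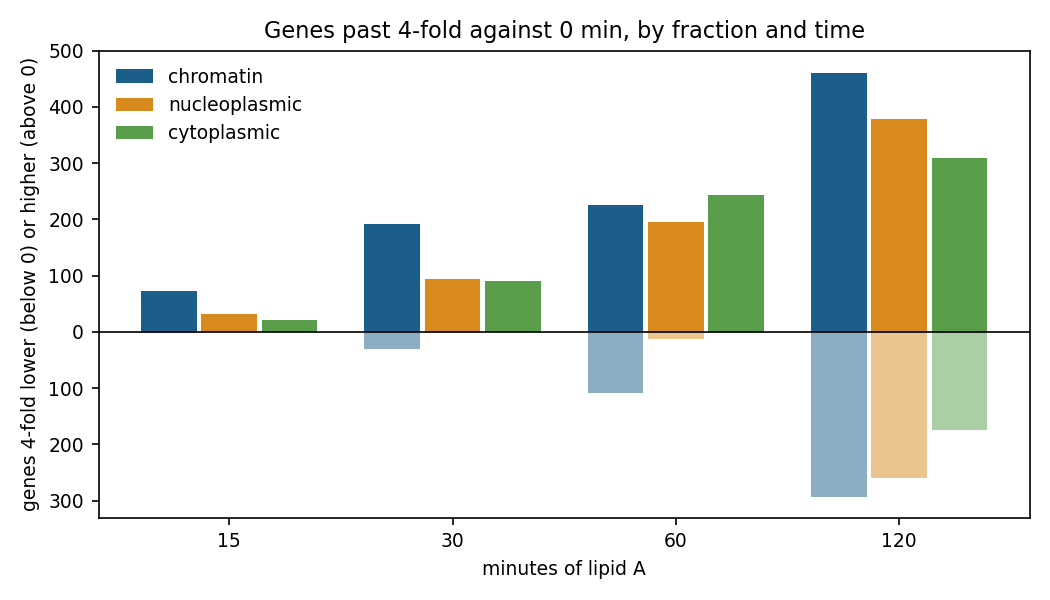
Number of genes 4-fold or more above (upward bars) or below (downward bars) the 0 min library, by fraction and minutes of lipid A. Chromatin RNA had 73 higher genes at 15 min against 22 in cytoplasmic RNA, and most lower genes appeared at 120 min.

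**Figure D3:**
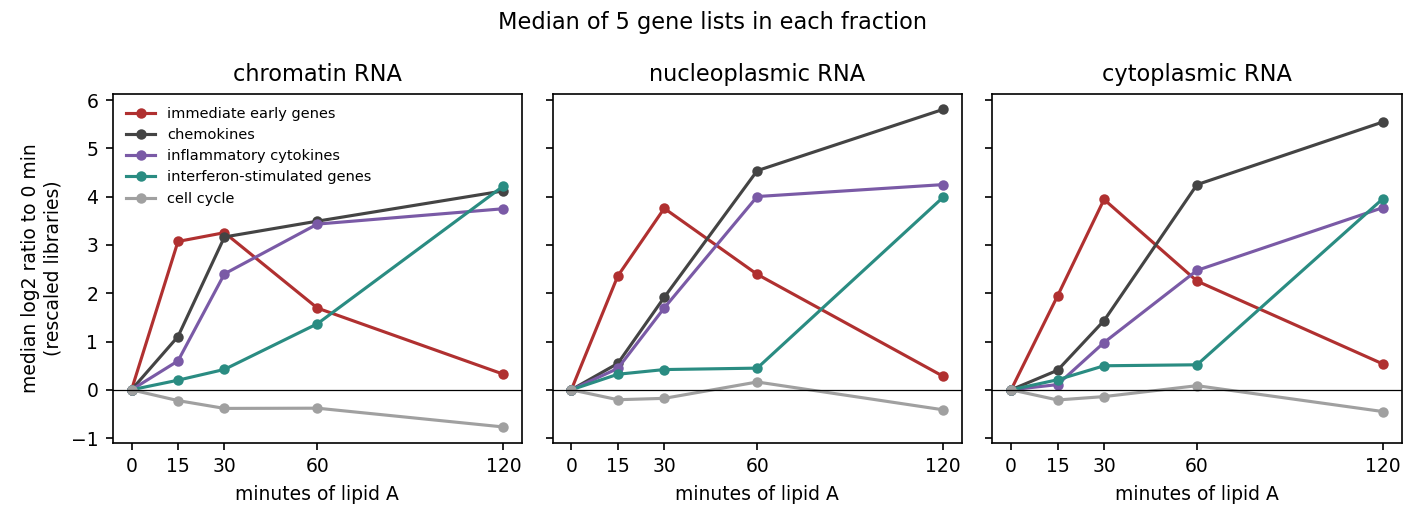
Median log2 ratio to 0 min of 5 gene lists after rescaling, against minutes of lipid A, with 1 panel per fraction and lines joining single libraries. Immediate early genes were highest by 30 min and interferon-stimulated genes at 120 min in each fraction.

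The order of events between fractions was compared for genes higher in both chromatin and cytoplasmic RNA. Egr1 was highest at 15 min in chromatin RNA and at 30 min in cytoplasmic RNA, while Tnf, Nfkbia, Il1b, Cxcl1 and Cxcl2 were highest at 30 min and at 60 min. Ccl5, Cxcl10, Ifit1, Il12b, Il6 and Nos2 were highest at 120 min in both, and Ifnb1 at 60 min in both. Rescaled, Nfkbia and Cxcl2 were highest at 30 min in cytoplasmic RNA and Il12b at 60 min in chromatin RNA. There were 356 such genes, against 26.7 expected from independent lists over 8307 genes. The cytoplasmic maximum came later for 95 (26.7%, exact 95% binomial interval 22.2% to 31.6%), at the same time for 246 and earlier for 15. In chromatin RNA 211 of the 356 genes were highest at 120 min, the last time sampled. They could not be highest later in cytoplasmic RNA, and these counts are without rescaling. The first time past 4-fold came earlier in chromatin RNA for 153 (43.0%, 37.8% to 48.3%), in both at once for 189 and earlier in cytoplasmic RNA for 14. A gene first past 4-fold in chromatin RNA at 120 min could not follow later in cytoplasmic RNA. Genes are not independent of each other, so the intervals are too narrow. The rescaled share past 4-fold earlier in chromatin RNA was 48.5%. In all 3 fractions together 324 genes were higher and 101 lower.

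The fraction comparisons asked which transcripts were distributed differently between compartments over the whole time course. Malat1, Neat1 and Xist, noncoding RNAs that act in the nucleus, were the lowest in cytoplasmic against chromatin RNA, with log2 differences of -6.04 ± 0.23, -6.00 ± 0.19 and -5.92 ± 0.18 (SE, 5 times per fraction). Malat1 averaged 27.3 ± 12.6 RPKM in cytoplasmic and 1663 ± 217 RPKM in chromatin RNA (SD, n = 5 times). At the other end were Atp5e, a subunit of mitochondrial ATP synthase, at 4.19 ± 0.20, and S100a9 at 4.06 ± 0.23. The limma adjusted p was 4.55e-16 for Malat1 and 3.96e-14 for Atp5e, with the same direction at all 5 times. In total the genes differing between cytoplasmic and chromatin RNA numbered 4330 of 9441, 3845 higher and 485 lower in cytoplasmic RNA. After quantile normalization, which removes the median difference of 0.76 on the log2 scale, 3233 differed, 1636 higher and 1597 lower.

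Among other genes higher in cytoplasmic than in chromatin RNA, Sh3bgrl3, a small thioredoxin-like protein, had a log2 difference of 3.93, the actin-binding gene Tmsb4x one of 3.82 and Actb one of 2.78. Of 24 oxidative phosphorylation genes 23 were higher and 0 lower, with Ndufa2 at 3.30 and Cox4i1 at 3.12, and the median was 2.48 (1.72 by quantiles). Cell cycle genes had 14 higher of 18, led by the cyclin gene Ccna2 at 3.07, and histones 10 higher of 12, led by Hist1h1a at 2.84. Nuclear noncoding RNAs had 5 lower of 6, snoRNA hosts 4 lower and 1 higher (Snhg6 at 1.95) of 7, with Gas5 at -5.19, and splicing factors 8 lower and 3 higher of 26, with the kinase gene Clk1 at -2.44. Other lower genes included Vmp1, an autophagy protein, at -3.70, Slc2a6 at -2.89, the interferon-induced genes Mx2 at -2.51 and Mx1 at -2.46, both entered as noncoding transcripts, and Cd86, a costimulatory ligand, at -2.07.

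Several inducible lists, such as chemokines and inflammatory cytokines, had few calls between cytoplasmic and chromatin RNA, against 4330 of 9441 among all genes tested. Immediate early genes, interferon-stimulated genes and the Toll-like receptor pathway were called at about the share of all genes. A fraction difference that varied between times, as when a gene rose at different times in the fractions, was harder to call. Immediate early genes had 9 higher and 0 lower of 20, with Ier2 at 1.55 and Junb at 1.51, though their median of 0.74 was 0.08 by quantiles. Inflammatory cytokines had 0 higher and 4 lower of 20, with the macrophage growth factor Csf1 at -1.29 and Il10 at -1.18, and chemokines 0 of 17 past the test. NF-kappaB genes had 1 higher, Nfkbib at 1.45, and 2 lower of 21, Icam1 at -1.49 and Nfkbid at -1.18. MAP kinase regulators had 2 higher of 10, Spry2 at 1.39 and Dusp6 at 1.25. Prostaglandin genes had 2 higher of 13, Alox5ap at 1.51 and Alox5 at 1.24, of leukotriene synthesis, and 1 lower, Ptgs2 at -1.30. Interferon-stimulated genes had 9 higher and 5 lower of 30, their median of 0.59 being -0.25 by quantiles, and the Toll-like receptor pathway 7 higher and 4 lower of 25. Macrophage identity had 7 higher and 4 lower of 23, surface receptors 1 higher and 3 lower of 20 (Cd86, Cd80 at -1.53 and Cd40 at -1.48), glycolysis 8 higher and 2 lower of 17, cholesterol synthesis 5 higher and 2 lower of 17, the secretory pathway 5 higher and 2 lower of 19, and housekeeping genes 10 higher and 1 lower of 15. Ribosomal proteins had 13 higher and 2 lower of 24, neutrophil markers 2 higher of 6, S100a9 and Ngp at 1.41, and T and B cell markers 0 of 2 each. By quantiles the medians of NF-kappaB, MAP kinase, macrophage identity, cholesterol, secretory, Toll-like receptor, T cell and B cell genes were negative instead of positive, and those of ribosomal proteins (1.20 and 0.57) and housekeeping genes (1.67 and 0.83) fell under 2-fold. Those of inflammatory cytokines (-0.50 and -1.04), surface receptors (-0.43 and -1.11) and splicing factors (-0.34 and -1.40) moved past 2-fold lower. Adjusted over the list alone, the counts of every list named here were identical in all 3 fraction comparisons.

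Several of these genes have near-identical copies elsewhere, so their values are uncertain. Gapdh averaged 0.0563 RPKM in cytoplasmic RNA, far below its known abundance, and 84.0% of its 32-base stretches also occurred in transcripts of other genes. The ribosomal protein gene Rplp1, with a log2 difference of 3.82, shared 74.1%. Actg1 at -3.47 and Hnrnpa1 at -2.34, which also have many processed copies, as well as the histones, Ftl1, Fth1 and Ptma, are to be read with the same care.

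In nucleoplasmic against chromatin RNA, Lamp1, a lysosomal membrane protein, was the highest at a log2 difference of 3.09 ± 0.25 (SE, 5 times, limma adjusted p = 2.74e-10), with the protease gene Ctss at 2.96 ± 0.24. Lyz2, the lysozyme of macrophages, was at 2.82 ± 0.27 and the protease inhibitor Cst3 at 2.84 ± 0.23. Xist was the lowest at -4.24 ± 0.18, with Gas5 at -3.09, Kcnq1ot1 at -2.36 and Malat1 at -2.07. In total the genes differing between nucleoplasmic and chromatin RNA numbered 4375, 4160 higher and 215 lower, with a median of 0.88 over all genes. By quantiles 1761 differed, 767 higher and 994 lower, so the number and the balance rest on the scaling.

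Among the lists, macrophage identity had 22 higher and 0 lower of 23 in nucleoplasmic against chromatin RNA, with the signalling adaptor Tyrobp at 2.80 and the pore-forming protein Mpeg1 at 2.68. The secretory pathway had 18 of 19, with the chaperone gene Hsp90b1 at 2.69 and the disulfide isomerase gene P4hb at 2.70, oxidative phosphorylation 23 of 24, cell cycle 15 of 18 and surface receptors 13 of 20. Nuclear noncoding RNAs had 0 higher and 5 lower of 6, snoRNA hosts 1 higher and 2 lower of 7 (Snhg6 at 1.33, Gas5 and Snhg1 at -1.53) and splicing factors 2 higher and 7 lower of 26, with Hnrnpl at 1.64 and Luc7l3 at -1.49. Chemokines had 6 higher of 17, cytokines 2 of 20, immediate early genes 3 of 20, MAP kinase regulators 1 of 10 and prostaglandin genes 6 of 13, with 0 lower in each. The medians of these 5 lists were positive but negative by quantiles (chemokines 0.87 and -0.39), as were those of the NF-kappaB, interferon-stimulated, Toll-like receptor and ribosomal protein lists. NF-kappaB genes had 1 higher and 1 lower of 21, interferon-stimulated genes 13 and 3 of 30, the Toll-like receptor pathway 9 and 1 of 25, glycolysis 12 and 1 of 17, cholesterol synthesis 10 and 0 of 17, histones 7 and 0 of 12, ribosomal proteins 10 and 1 of 24 and housekeeping genes 11 and 1 of 15. Neutrophil markers had 6 higher of 6, T cell markers 1 of 2, Cd28 at 2.44, and B cell markers 2 of 2, Cd79b at 2.45 and Cd22 at 1.36. These counts are without quantiles, by which the medians of further lists fell from past 2-fold to under it: macrophage identity from 2.18 to 0.60, the secretory pathway from 2.48 to 0.81, surface receptors from 1.51 to 0.24, cell cycle from 1.52 to 0.62, glycolysis from 1.66 to 0.61, cholesterol synthesis from 1.56 to 0.29, histones from 1.44 to 0.43, housekeeping genes from 1.95 to 0.35 and T cell markers from 1.19 to 0.29. Oxidative phosphorylation (2.19 and 1.04), neutrophil markers (2.09 and 1.22) and B cell markers (1.90 and 1.27) stayed past it. The medians of NF-kappaB genes (0.09 and -1.28), splicing factors (-0.28 and -1.47) and snoRNA hosts (-0.56 and -1.20) moved past 2-fold lower.

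In cytoplasmic against nucleoplasmic RNA, Glg1, a Golgi protein, was the lowest with a log2 difference of -4.11 ± 0.20 (SE, 5 times, limma adjusted p = 2.64e-13) and the integrin gene Itgb7 had one of -4.01 ± 0.22. Hsp90b1 and Hspa5, chaperones of the endoplasmic reticulum, were at -3.79 ± 0.22 and -3.77 ± 0.21, close to Neat1 and Malat1, both at -3.97. The highest were Hist2h3b at 2.24 ± 0.26, Rplp1 at 2.14 ± 0.25 and the ferritin gene Ftl1 at 2.12 ± 0.19. In total the genes differing between cytoplasmic and nucleoplasmic RNA numbered 2009 of 9441, 440 higher and 1569 lower, and by quantiles 2126 differed, 757 higher and 1369 lower.

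Many receptor transcripts were lower in cytoplasmic than in nucleoplasmic RNA. Surface receptors had 17 lower and 0 higher of 20, with Cd86 at -2.81. Macrophage identity had 16 lower and 1 higher of 23, with the mannose receptor Mrc1 at -3.64 and the integrin Itgam at -3.46. The secretory pathway had 14 lower and 1 higher of 19 with a median of -2.29 (-1.82 by quantiles), and the Toll-like receptor pathway 10 lower and 1 higher of 25, with Tlr7 at -2.87 and Tlr2 at -2.83. Cytokines had 9 lower of 20, with Csf1 at -2.27 and Tnf at -1.16, chemokines 6 of 17, prostaglandin genes 8 of 13, cholesterol synthesis 8 of 17, and glycolysis 3 of 17, with the transporter Slc16a3 at -2.64. Within 4 of the lists, 43 of 45 members made on the endoplasmic reticulum or inserted into its membrane and 0 of 39 other members were called lower. Immediate early genes had 0 of 20 past the test in either direction, NF-kappaB genes 1 higher, Bcl3 at 1.27, and 1 lower of 21, the adhesion molecule Icam1 at -2.84, MAP kinase regulators 1 higher of 10, Dusp5 at 1.08, and interferon-stimulated genes 4 lower of 30, Rsad2 at -1.37, Igtp at -1.22, Gbp2 at -1.07 and Mx1 at -1.06. Cell cycle had 1 lower of 18, Mki67 at -1.33, splicing factors 1 lower of 26, Clk1 at -1.01, noncoding RNAs 4 lower of 6, snoRNA hosts 3 lower of 7, histones 5 higher of 12, ribosomal proteins 5 higher and 1 lower of 24, oxidative phosphorylation 2 higher of 24 and housekeeping genes 1 higher and 2 lower of 15. Neutrophil markers had 1 higher, S100a9 at 1.22, and 3 lower of 6, Mmp8 at -2.78, Ltf at -1.92 and Mpo at -1.07, T cell markers 1 lower of 2, Cd28, and B cell markers 2 lower of 2, Cd79b and Cd22. By quantiles the medians of the Toll-like receptor, glycolysis and splicing factor lists were positive instead of negative, and those of prostaglandin genes (-1.28 and -0.90) and neutrophil markers (-0.83 by quantiles) fell under 2-fold. That of histones (0.75 and 1.18) moved past 2-fold higher.

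The series names nascent transcripts and RNA processing as its subject, and intron to exon read density was compared between fractions for the inducible genes. Intron reads were all reads of the whole gene outside the listed exons, so the measure is not a share of unspliced RNA. In 305 genes, intron read density was 0.403 ± 0.0914 of exon density in chromatin RNA (mean of the medians ± SD, n = 5 times), 0.0435 ± 0.0208 in nucleoplasmic RNA and 0.00972 ± 0.00375 in cytoplasmic RNA. Chromatin RNA was 10.0-fold above nucleoplasmic RNA, from 7.28-fold to 15.5-fold over the times, and nucleoplasmic RNA 4.33-fold above cytoplasmic RNA, from 2.05-fold to 7.73-fold. Each difference had the same direction at all 5 times, with an exact two-sided sign-flip p of 0.0625, the smallest that 5 pairs allow. In chromatin RNA the median was 0.341 at 0 min, 0.485 at 15 min, 0.480 at 30 min, 0.431 at 60 min and 0.276 at 120 min.

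**Figure D4:**
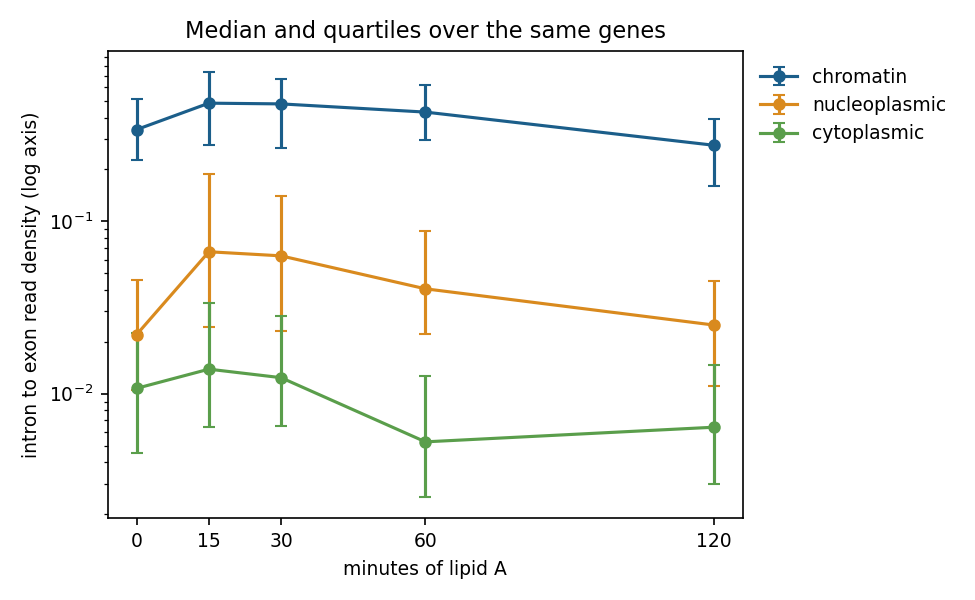
Intron to exon read density (log axis) against minutes of lipid A for the same 305 genes, as the median (point) and quartiles (bars) over genes in 3 fractions. Chromatin RNA lay above nucleoplasmic RNA and nucleoplasmic above cytoplasmic RNA at every time.

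The 560 inducible genes came in classes in the authors' deposited table, A1 (16 genes), A2 (58), B (56), C (98), D (97), E (116) and F (119). The classes were made from these libraries, so their time courses are not independent evidence. RPKM in this paragraph are relative to the whole gene, introns included. Their levels are not to be set against exon RPKM or between classes that differ in gene length. Median chromatin RPKM was highest at 15 min in A1, at 30 min in A2 and C, at 60 min in B and at 120 min in D, E and F. Median cytoplasmic RPKM was highest at 30 min in A1, at 60 min in A2, B and C and at 120 min in D, E and F. Rescaled, B and C were highest at 120 min instead, with medians of 0.777 RPKM at 60 min and 1.06 RPKM at 120 min in B, and 8.09 and 10.2 RPKM in C. In the authors' deposited table the share of promoters marked as low in CpG was 12.5% in A1, 15.5% in A2, 28.6% in B, 41.8% in C, 51.5% in D, 48.3% in E and 63.9% in F. Over all classes the 310 genes with CpG promoters had a median of 0.849 RPKM at 0 min in chromatin RNA. Their median highest fold, taken without a pseudocount, was 9.59. The 250 genes with low-CpG promoters had 0.526 RPKM and 17.7-fold.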

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

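The chromatin library of 120 min stood apart from the other 4 chromatin libraries in the percent of its reads that fell on the listed exons. It was 27.2%, against 20.6% to 21.9% in the others, and the gap was 0.809 of the whole range, above the 95% critical value of 0.71 for 5 libraries. It was 1 of 15 sets of libraries examined this way, and chance marks about 1 in 20 sets. Without this library 285 genes were higher and 122 lower after lipid A in chromatin RNA. No gene was 4-fold or more higher in a fraction and 4-fold or more lower in another at the same time.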

How the results depend on the processing

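The alternative without both the 60 and 120 min libraries was chosen only after the data were seen. Of the values that answer a comparison, 99 stayed within 1.5 times or the interval of the value reported and 26 did not, and for these the cause was not tested. The balance of higher and lower genes turned with a pseudocount of 0.1 RPKM in chromatin and nucleoplasmic RNA and with quantile normalization in nucleoplasmic against chromatin RNA. With a pseudocount of 0.1 RPKM the genes lower after lipid A were 1028 in chromatin, 631 in nucleoplasmic and 404 in cytoplasmic RNA, and with 1 RPKM 159, 152 and 95. A minimum of 5 RPKM, which tests fewer genes, left 215 lower in chromatin RNA. Rescaling gave 220, 148 and 97 lower, and the share of genes called higher first in chromatin RNA was then 48.5%. Past 4-fold at 2 or more times, 215 genes were higher and 75 lower in chromatin RNA, 163 and 10 in nucleoplasmic RNA, and 176 and 2 in cytoplasmic RNA. Without both the 60 and 120 min libraries, 90 were higher and 1 lower in cytoplasmic RNA. The genes differing between nucleoplasmic and chromatin RNA numbered 1761 by quantile normalization, 767 higher and 994 lower. Leaving out 1 stimulated library at a time gave 285 to 574 higher and 122 to 347 lower genes in chromatin RNA, 202 to 450 and 12 to 262 in nucleoplasmic RNA, and 249 to 414 and 2 to 174 in cytoplasmic RNA. Each lowest value was that without the 120 min library. Leaving out a time point gave 3945 to 4612 genes between cytoplasmic and chromatin, 4221 to 4643 between nucleoplasmic and chromatin and 1906 to 2207 between cytoplasmic and nucleoplasmic RNA. Over rescaling and a pseudocount of 1 RPKM, list medians moved in 14 cases and did not in 120, and over these and other alternatives values of named genes moved beyond their counting interval in 695 cases and did not in 552. Depth limits the weakly expressed genes: with 1 to 3 reads at 0 min, as for Ifnb1 and Il6, a ratio is known only within its wide counting interval.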

Other observations

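Of the tests given here, those of the 27 listed ribosomal protein genes, of the cytoplasmic shift against the share of reads on listed exons, of the endoplasmic reticulum, of later release and of other splits of the libraries were chosen after the results had been seen.

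Some genes that were lower after lipid A were called lower in chromatin RNA before they were in cytoplasmic RNA. Of the 112 genes lower in both, the first call came earlier in chromatin RNA for 35, at the same time for 77 and earlier in cytoplasmic RNA for 0, and of the 60 lower in both when rescaled for 15, 45 and 0. A gene first called lower in chromatin RNA at 120 min, the last time sampled, could not be called later in cytoplasmic RNA. Zfp36l2 stood at 4.43 RPKM at 15 min against 20.1 RPKM in chromatin RNA, but at 39.6 RPKM against 24.4 RPKM in cytoplasmic RNA, where it was 0.970 RPKM at 120 min. Txnip was at 35.0 RPKM at 15 min against 113 RPKM in chromatin RNA, short of 4-fold, and at 78.3 RPKM against 79.7 RPKM in cytoplasmic RNA. Its first call came at 30 min in both fractions, with 16.4 RPKM in cytoplasmic RNA. Dusp6 was at 3.87 RPKM at 15 min against 11.3 RPKM in chromatin RNA, also short of 4-fold, and at 16.2 RPKM against 10.7 RPKM in cytoplasmic RNA. Vmp1, in contrast, was at 104 RPKM at 15 min against 30.9 RPKM in chromatin RNA and between 2.94 and 6.20 RPKM in cytoplasmic RNA at all times. These 4 genes were chosen after their values were seen, as was the count.

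Intron density in chromatin RNA was highest at different times in the classes of inducible genes in the authors' deposited table. The median ratio of intron to exon density over the genes with enough exon reads in all 5 chromatin libraries, from 10 in A1 to 73 in F, was highest at 15 min in A1 (0.779, against 0.755 at 0 min), A2 (0.708) and C (0.742), at 30 min in B (0.690) and D (0.541), and at 60 min in E (0.536) and F (0.383). The classes were made from these libraries.

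Most cytoplasmic values were higher at 60 min and lower at 120 min than at 0 min, with library shifts of 0.47 and -0.48 on the log2 scale. At 60 min the share of reads on listed exons was higher by 0.65 on the log2 scale, which left a shift of -0.18, but values relative to library reads rise with this share by construction, so it cannot be told apart from a rise of the genes themselves. At 120 min the share was higher by 0.06, against the direction of the shift, and left -0.53. That share includes the growing reads of genes called higher, so it does not show the share of the other genes and cannot decide there. Taking out the reads of genes called higher, which went from 0.694% to 6.52% of the library, left -0.39 at 120 min, so these reads account for less than 0.5 of the shift. The design gives no biological group to set against time itself, and a loss of cytoplasmic RNA over time stays open as untested.

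Ribosomal protein genes had very different levels in cytoplasmic RNA, such as 0.496 RPKM for Rps18, with 90.5% of its 32-base stretches shared with other genes, and 112.68 RPKM for Rpl8, with 8.19% shared. Over the 32 genes of the list, Spearman's rho of shared stretches with level was -0.48 (permutation p = 0.00611), short of the bound of -0.5 set in advance for reads lost to near-identical copies. This entered 5 genes that the table does not list at 0 RPKM. Over the 27 with a value, a choice made after the result was seen, rho was -0.70 (permutation p = 4e-05), past the bound. The table lists only genes at 1.00 RPKM or more in some library, so leaving out the 5 selects on level, and the explanation cannot be told apart from others. Transcript length had a rho of 0.16 over the 32 genes (permutation p = 0.374) and 0.18 over the 27 (permutation p = 0.373), below the 0.2 set in advance but not by more than the spread, so it stays open too. Genes are not independent replicates. No biological explanation was tested.

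In 4 lists that hold both kinds of protein, transcripts of membrane and secretory pathway proteins were lower in cytoplasmic than in nucleoplasmic RNA. The median log2 difference was -2.61 over 45 members made on the endoplasmic reticulum or inserted into its membrane and 0.32 over 39 others, a difference of -2.93 (permutation p = 1e-05, the smallest that the permutations can give), and 43 against 0 were called lower. In lists of secreted proteins the difference was smaller: 6 of 17 chemokines were called lower with a median of -0.91 (-0.28 by quantiles), and 9 of 20 inflammatory cytokines with a median of -0.69 (-0.34 by quantiles). In the Toll-like receptor pathway the medians were -2.62 and 0.48, and among macrophage identity genes -2.50 and 0.62. A candidate explanation is that endoplasmic reticulum with its ribosomes stayed with the nuclei during fractionation, and it leaves the smaller difference of chemokines and cytokines open. Later release from the nucleus cannot be told apart from it. The cytoplasmic maximum came later than the nucleoplasmic for 3 of 31 chemokines and cytokines and 4 of 35 immediate early and NF-kappaB genes, a difference of -1.75 percentage points, but 17 of the 31 were highest in nucleoplasmic RNA at 120 min, the last time sampled, and 0 of the 45 members were among them.

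The lag between the first call in chromatin and in cytoplasmic RNA was set against the length of the gene. Over 286 genes Spearman's rho was 0.17 (permutation p = 0.0039), between the 0.1 and 0.2 set in advance. Genes first called in chromatin RNA at 120 min, the last time sampled, could not show a lag and were entered without one. Longer genes had a lag more often, but the time of the first call was not separated from length. Whether length is the cause stays open, and genes are not independent replicates. A lag was present in 36 of the 96 shortest genes and 49 of the 96 longest.

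For the fraction comparisons, libraries were swapped between the fractions within each time, since time was a term of the fit. The 5 times allow 16 such splits, too few for a share under 0.05. In each comparison only 1 split, the real one, reached the real count. It called 4324 genes in cytoplasmic against chromatin RNA, 4363 in nucleoplasmic against chromatin RNA and 1999 in cytoplasmic against nucleoplasmic RNA, and the highest other called 0 in each. Among 100 splits of the 10 libraries that ignored time, the highest other called 4523, 4170 and 1 genes in the same order. That of 4523 kept 4 cytoplasmic libraries (0, 15, 30 and 60 min) together with the chromatin library of 0 min, or the reverse with chromatin libraries, so it differed from the fractions by 1 library on each side.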
